A study of Mus musculus with 4 samples.

How the data were processed

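RNA from 4 samples of E14Tg2A.4 mouse embryonic stem cells, 2 treated with BMP-2 at 25 ng/ml for 1 h and 2 untreated, was labelled with biotin as cRNA from total RNA and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are linear intensity signals per probe set made with MAS5, per the submitters' processing notes, in a version not given in the sources used here. MAS5 summarises each probe set from its perfect-match and mismatch probes, and low signals are noisy on a log scale. The deposited values hold no 0 and no negative signal, and their 2%-trimmed mean was 500 on each array, from which a scaling within each array was read. Detection calls were not used here, so brightness stood in for detection. Samples were grouped by their titles, and no other columns were present.

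Signals were taken as log2 with no pseudocount. The medians of the 4 arrays lay within 0.21 log2 of one another, under the limit of 0.3 set before the data were examined, so no further normalization was applied. After 64 control probe sets had been left out, probe sets were kept when their mean log2 signal over the 4 arrays was above its 40th percentile, which is 5.73 log2 or a signal of 53.0. Of the 27022 kept, 22983 have 1 gene symbol in the platform annotation, 630 have several and 3409 have none. Over all probe sets other than controls these numbers are 34945, 932 and 9160. Updating symbols through Entrez identifiers, with the gene table of assembly GRCm38.p6, changed 0 symbols. The array values name no genome build, so coordinates were not used here. The kept probe sets represent 12976 genes. For lists and named genes, a gene was represented by its kept probe set with the highest mean signal among those that name it alone, or, for genes past the threshold, by the passing one. Folds are 2 to the power of the log2 difference.

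Treated and untreated arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the variance on signal), with no replicate block, two-sided and with Benjamini-Hochberg adjustment over all kept probe sets. Every adjusted p for a gene comes from this fit unless said otherwise. The fit had 2 residual and 7.98 prior degrees of freedom, so the error of a gene is mostly borrowed from probe sets of like signal. Means are given with the SD over 2 arrays, and intervals are at 95%. With 2 arrays per group a permutation of the labels cannot pass a threshold of 0.05 for a single gene, and none was run.

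A total of 22 gene lists were written from general knowledge before the data were examined. They cover BMP, Nodal, MAPK, LIF, Notch and Wnt signalling, pluripotency, lineage and feeder cell markers, stress, metabolism, cell cycle, ribosomal and reference genes. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 22 lists. Camera asks whether a list shifted relative to the other genes. With an estimated correlation 0 of the 22 lists passed (1 at an unadjusted p under 0.05, the early BMP targets), fry, which asks whether genes of a list move on balance one way, called 1, and its test for either direction called 2. The genes named were set by a rule fixed beforehand. It takes all genes past the threshold, then enough of the smallest p-values among genes at least 0.58 log2 (1.5-fold) apart whose groups did not overlap to reach 20, as many higher as lower. It adds the 12 brightest measured members of the early BMP list and up to 4 members of each other list with the smallest p. This gave 106 genes, of which the text gives examples. Another 8 (Pou5f1, Nanog, Sox2, Egr1, Fos, Msx2, Id4 and Cdc42ep5, the last on its dimmer probe set) were chosen after their values were seen.

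The alternatives were quantile normalization, median centring, a pseudocount of 25.4 (the 25th percentile of all signals), no filter, a filter at the 60th percentile, no intensity trend, the replicate number as a block, leaving out each array, adjusted p under 0.1, a difference of at least 1 log2, other list tests, and the mean of a gene's probe sets. The early BMP list without Id1, Id2 and Id3 was added after seeing the data. The folds with signals raised to the signal limit, for genes with a group below it, were also set after the values were seen. The fit itself used the measured signals.

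The fit was tested on simulated data for 27022 probe sets with 200 of them changed, in 5 runs. It recovered 16.8% of changes of 0.5 log2, 46.4% of 1 log2, 75.2% of 1.5 log2 and 86.8% of 2 log2, and 5.06% of its calls were false. A simulated shift of the early BMP list by 0.5 log2 was found by camera in 5 of 5 runs, by camera with an estimated correlation in 0 and by fry in 2. A list that does not pass with an estimated correlation is thus not shown to be unshifted. The simulated noise was drawn from the spread fitted here, independent between probe sets and with no replicate-number effect. These rates thus check the code and do not give the error rates on the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.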

Results

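Transcript levels were measured on 4 one-colour Affymetrix arrays hybridised with RNA from E14Tg2A.4 cells, a subline of the Hprt-deficient mouse embryonic stem cell line E14Tg2a. The cells of 2 arrays had received bone morphogenetic protein 2 (BMP-2), a secreted ligand that signals through the transcription factors SMAD1 and SMAD5, at 25 ng/ml for 1 h. The cells of the other 2 arrays were untreated. The arrays carried 45101 probe sets, and 27022 of them were bright enough to be tested. Median signals over all deposited probe sets were 81.8 and 94.9 on treated replicates 1 and 2, and 82.5 and 94.6 on untreated replicates 1 and 2. The number of arrays limits the precision of every value below. Log2 signals correlated across probe sets at r = 0.985 within each group and at 0.984 to 0.987 between arrays of different groups, and probe sets are not independent replicates. The SD over probe sets of the log2 difference between 2 arrays was 0.37 within each group and 0.34 to 0.38 between groups. The lowest values, 0.34 and 0.35, were those of the arrays with equal replicate number. On untreated replicate 2 the 18S ribosomal RNA control probe sets read 6.11, 3.94 and 4.13 times the highest of the other arrays, and the ratios of 3' to 5' signal for Actb, Gapdh and Tfrc on that array were 1.08, 1.01 and 1.16 times the mean of the others. Nothing in the labels states that the arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

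The comparison of treated with untreated cells asked which transcripts differed after 1 h of BMP-2. Transcripts of Id1, Id2 and Id3, which encode helix-loop-helix proteins that block DNA binding by basic helix-loop-helix factors and are known early targets of BMP signalling, rose in treated cells. The Id1 signal was 9617 ± 172 (SD, n = 2) with BMP-2 and 3068 ± 86.3 (SD, n = 2) without, a 3.14-fold rise (95% interval 2.80 to 3.51). Id2 rose 3.38-fold (2.93 to 3.91), from 1436 ± 8.70 to 4865 ± 452, and Id3 rose 3.32-fold (2.9 to 3.81), from 1083 ± 17.2 to 3599 ± 29.7. A probe set of Pom121, which encodes a membrane protein of the nuclear pore, rose 1.71-fold (1.5 to 1.95), from 2548 ± 146 to 4359 ± 82.2. The other tested probe set of Pom121 differed by -0.05 log2.

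By limma, 5 probe sets passed an adjusted p of 0.05, all of them higher with BMP-2 and above both untreated arrays on both treated arrays. The log2 differences were 1.65 ± 0.07 (SE, adjusted p = 2.0e-05) for Id1, 1.76 ± 0.09 (adjusted p = 3.6e-05) for Id2, 1.73 ± 0.09 (adjusted p = 3.6e-05) for Id3 and 0.78 ± 0.08 (adjusted p = 0.0175) for Pom121. A second Id2 probe set was the fifth, at 1.15 log2 (adjusted p = 0.0085), and a dimmer one gave 0.99 log2 (adjusted p = 1.00). The other Pom121 probe set differed by -0.05 log2 (adjusted p = 1.00), so the call belongs to 1 of the 2 Pom121 probe sets, and the mean of both gave 0.36 log2. At an unadjusted p under 0.05 there were 829 probe sets, 517 higher and 312 lower. This is a smaller share of the tested probe sets than the 0.05 that chance alone gives. With the replicate number as a block there were 1452, above that share. Treated and untreated signals did not overlap for 7672 probe sets, or 28.4%, where chance gives 33.3%. This comparison makes no allowance for the replicate number. No probe set passed when the spread was modelled without its trend on signal (0, with 1023 at an unadjusted p under 0.05), and centring each array on its median gave 17 probe sets, 12 higher and 5 lower, against 5 higher and 0 lower. Leaving out an array left 1 array in a group. The log2 differences then ran from 1.62 to 1.68 for Id1, 1.66 to 1.85 for Id2, 1.72 to 1.75 for Id3 and 0.72 to 0.83 for Pom121. In these fits more probe sets passed than in the main fit, with less weight on the spread of a single probe set. The counts of alternatives passed below include them, so a count does not measure how firm a difference is. Of 114 genes followed over the alternatives, the log2 difference of 75 moved by over 1.5 times or changed sign in some setting. For those given below by a log2 difference, its range over the alternatives follows the value. Some groups had a mean signal below the lower signal limit of the tested probe sets. For these, signals under the limit were raised to it, and the fold is given as a value with raised signals. This fold allows for the dim signals alone and not for the spread between arrays, so it is not a minimum.

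**Figure D1:**
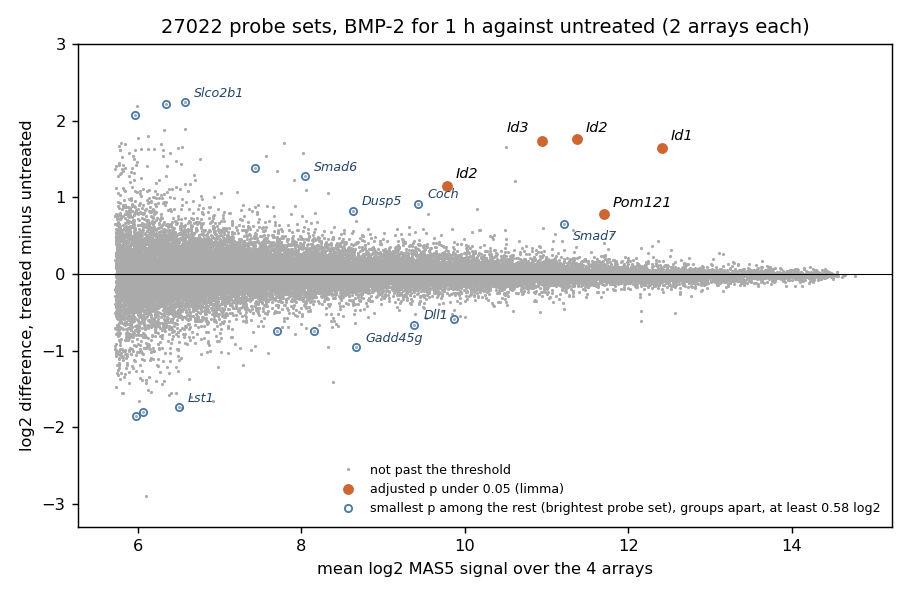
Log2 difference between BMP-2 treated and untreated cells (vertical axis) against the mean log2 MAS5 signal over the 4 arrays (horizontal axis) for 27022 probe sets, each a point. Filled circles mark the 5 probe sets with an adjusted p under 0.05 (limma), at 0.78 to 1.76 log2, and open circles 16 genes taken by smallest p on the brightest probe set of a gene, 8 higher and 8 lower, among the rest that differed by at least 0.58 log2 and whose groups did not overlap. For 6 of these the mean of 1 group lay below the lower signal limit, so that the plotted difference is not measured on both sides.

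The early BMP and SMAD1/5 target genes were higher as a list after BMP-2 by camera of limma (adjusted p = 5.0e-17). With an estimated correlation the list did not pass (adjusted p = 0.235). The estimated correlation was -0.02, below the preset 0.01, so correlation among these genes does not account for the weaker p. That setting found a simulated shift of this list by 0.5 log2 in 0 of 5 runs, so it does not decide. Of its 30 genes 21 were measured, and 15 of these were higher and 6 lower in treated cells. Over all probe sets, 3 rose (Id1, Id2 and Id3) and 18 did not pass. Adjusted over the list alone, 10 passed and all 10 were higher, which adds Smad6 and Smad7, inhibitory SMADs that dampen BMP signalling, Bambi, a decoy receptor, Skil, a SMAD co-repressor, the homeobox genes Msx1 and Msx2, and Id4. Smad6 read 411 ± 34.7 against 170 ± 2.53 (1.27 log2, limma adjusted p over all probe sets = 0.062) and Smad7 2970 ± 20.2 against 1887 ± 118 (0.66 log2, range 0.41 to 0.72, adjusted p = 0.064). Smad6 passed in 7 and Smad7 in 4 of 12 alternative settings, fits without 1 array among them, and neither passed without the intensity trend. The difference was 0.59 log2 for Bambi, 0.43 for Skil, 0.66 for Msx1, 0.80 for Msx2 and 0.78 for Id4 (range 0.43 to 1.14). Skil and Id4 passed in 1 alternative each. Msx2 and Id4 were named after their values were seen. Other probe sets gave 0.38 log2 for Skil, 0.46 for Msx1, and 1.54 and 0.68 for Id4, while a second Smad7 probe set gave 0.16. Among the bright members of the list that did not pass, the differences were 0.22 log2 for Gata2, 0.09 for Smurf2, -0.02 for Tob1 and -0.10 for Smurf1, each smaller than or near its SE of 0.19, 0.18, 0.13 and 0.14, with ranges of 0.040 to 0.41, -0.17 to 0.35, -0.20 to 0.15 and -0.21 to 0.0078. The mean difference of the list was 0.49 log2 and the median 0.26, and fry gave an adjusted p of 0.0318. Without Id1, Id2 and Id3, a choice made after seeing the data, the mean of the other 18 genes was 0.28 log2 (camera adjusted p = 2.8e-06).

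**Figure D2:**
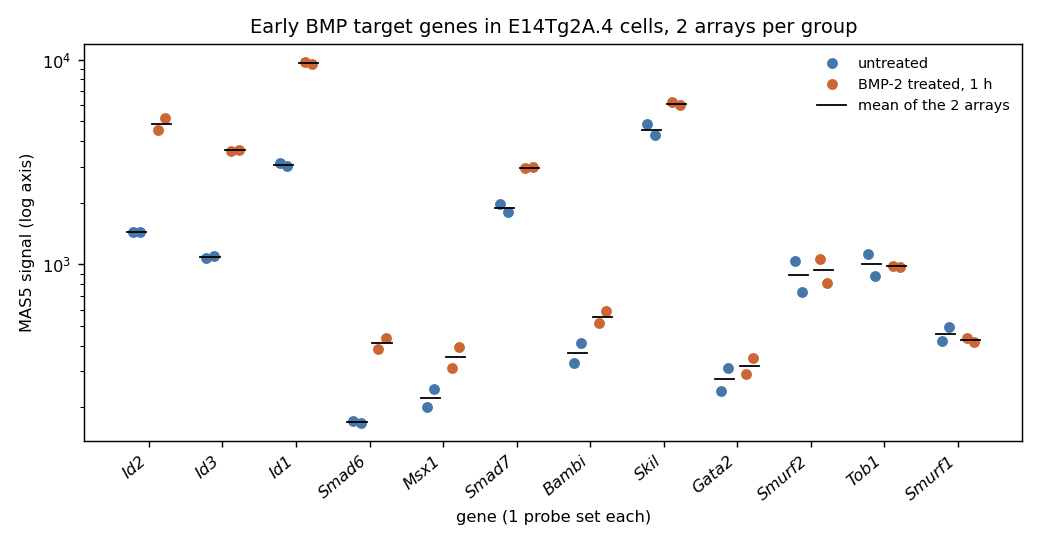
MAS5 signal (vertical log axis) of the 12 brightest measured early BMP target genes, ordered by log2 difference, with 1 point per array for 2 untreated and 2 BMP-2 treated arrays and a bar at the mean of each pair. Both treated points lie above both untreated points from Id2 (4865 against 1436 on average) to Skil (6104 against 4553), and the groups overlap for Gata2, Smurf2, Tob1 and Smurf1.

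Outside that list, the genes with the smallest p among those not past the threshold, at least 0.58 log2 apart on the gene's brightest probe set and without overlap between the groups, are given as values. Higher signals with BMP-2 were seen for Coch, Slco2b1 and Dusp5. Coch, which encodes cochlin, an extracellular matrix protein, read 946 ± 36.9 against 502 ± 2.22 (0.91 log2, limma adjusted p = 0.056). Slco2b1, an organic anion transporter, read 210 ± 45.9 against 44.1 ± 7.5 (adjusted p = 0.063). It lay 3.91-fold higher with raised signals, with an interval of 2.96 to 7.56 for the measured fold. Dusp5, a phosphatase that acts on ERK, read 528 ± 65.2 against 297 ± 5.02 (0.82 log2, adjusted p = 0.423). With raised signals Cphx3 and Hsd11b1 lay 3.30-fold and 2.43-fold higher (adjusted p = 0.133 and 0.466). The intervals of their measured folds were 2.74 to 7.86 and 2.28 to 7.81. Hs3st2 lay 1.38 log2 higher (range 0.43 to 1.55, adjusted p = 0.138). Lower signals were seen for Gadd45g, a growth arrest and stress response gene (293 ± 3.72 against 568 ± 36.9, -0.95 log2, adjusted p = 0.126), and for Dll1, a Notch ligand (531 ± 39.6 against 842 ± 38.6, -0.67 log2, adjusted p = 0.433). With raised signals Lst1, Trpc7 and Gapdhs lay 3.08-fold, 2.37-fold and 2.27-fold lower. The intervals of their measured folds were 2.13 to 5.23, 2.03 to 6.03 and 2.03 to 6.49. Cog8, Them6 and Msc differed by -0.59, -0.75 and -0.74 log2 (adjusted p 0.214 to 1.00 for these 6). Other probe sets went the opposite way for Cphx3 (-0.24 log2, with 0.99 log2 as the mean of its probe sets) and Hs3st2 (-0.52 log2), and gave -0.09 and -0.97 log2 for Cog8. In alternative settings Coch passed in 8 of 12, Slco2b1 in 5 and Cphx3 in 4 of 11, and Hs3st2, Gadd45g and Lst1 in 3 each. Trpc7 passed in 2, Dusp5, Hsd11b1, Dll1 and Gapdhs in 1 each, and Cog8, Them6 and Msc in 0. These counts include the fits without 1 array, where more probe sets passed than in the main fit. The choice of the brightest probe set passed over 9 dimmer probe sets of a gene (2 higher, 7 lower) and 5 without a gene of their own (1 higher, 4 lower) with p-values as small. The smallest p among these was that of Cdc42ep5, an effector of the small GTPase CDC42, named after its value was seen. It read 25.4 ± 5.29 against 189 ± 45.8 (adjusted p = 0.056), 3.52-fold lower with raised signals (measured interval 4.22 to 13.1). It passed in 7 of 11 alternatives, fits without 1 array among them, and did not pass without the intensity trend. The brighter Cdc42ep5 probe set differed by 0.05 log2 (adjusted p = 1.00) and the mean of both by -1.42 log2.

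No list of another signalling pathway passed by camera in the main setting, and the Nodal and TGF-beta list passed without the filter on dim probe sets (adjusted p = 0.0373, 0.0373 to 0.750 over all alternatives). Among BMP ligands, receptors and SMADs, 10 of 16 genes were higher and 6 lower and none passed, with -0.37 log2 for Bmp4 and 0.38 for Smad1 (camera adjusted p = 0.799). Of 13 Nodal and TGF-beta target genes 9 were higher, and none passed over all probe sets. Adjusted over the list alone, Lefty2, a Nodal antagonist, at 0.55 log2 (range 0.35 to 0.74) and Fgf15 at 0.46 passed, while Nodal itself differed by -0.19 (range -0.22 to -0.09) on its brighter probe set and 0.00 on the other (camera adjusted p = 0.127, fry adjusted p for either direction = 0.0462). Of 39 immediate-early and MAPK feedback genes 21 were higher and 18 lower, and adjusted over the list alone Dusp5 passed (camera adjusted p = 0.636). Dusp6 differed by 0.36 log2 (range 0.21 to 0.50), Spred2 by 0.22 (range 0.12 to 0.23) and Fosl1 by 0.56. Egr1 (0.07, range -0.21 to 0.36) and Fos (0.23, range -0.029 to 0.50), named after their values were seen, took the opposite sign when an array was left out. That also leaves the replicate numbers unequal between the groups. Between arrays of equal number neither gene was lower with BMP-2. Egr1 read 2768 against 2502 and 1859 against 1858, and Fos 285 against 270 and 246 against 188. The Notch list holds ligands (Dll1, Dll3, Jag1 and Jag2) and receptors (Notch1 and Notch3) beside target genes, so it does not measure target output alone. Of its 13 measured genes 7 were higher and 6 lower (camera adjusted p = 0.663). Dll1 was lower when adjusted over the list alone, Notch1 lay at -0.30 (range -0.44 to -0.05) and Nrarp at 0.36 (range 0.20 to 0.52). Of 12 Wnt target genes 7 were higher and 5 lower, with a mean of -0.06 (camera adjusted p = 0.915). Sp5 lay at -0.52 (range -0.81 to -0.22), Notum at -0.16 (range -0.22 to -0.10), Axin2 at 0.28 (range 0.063 to 0.49) and Lef1 at 0.27.

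Pluripotency genes did not pass over all probe sets. Of 28 measured, 15 were higher and 13 lower (camera adjusted p = 0.566, but 0.0087, with a mean of -0.06 log2, without untreated replicate 2, and 0.0087 to 0.988 over all alternatives). Pou5f1 and Nanog, core pluripotency factors named after their values were seen, differed by 0.05 log2 each with intervals of -0.10 to 0.20 (ranges 0.0090 to 0.09 and 0.0025 to 0.10). Sox2, likewise named afterwards, differed by 0.01 log2 (range -0.019 to 0.049), or -0.02 after centring each array on its median. Gbx2, a homeobox gene held by the pluripotency, LIF and neuroectoderm lists, read 846 ± 61.1 against 1250 ± 181 (-0.56 log2, limma adjusted p = 0.910) and passed when adjusted over each of these lists alone. Tbx3 differed by 0.36 log2, Nr0b1 by -0.20 (range -0.29 to -0.11) and Nr5a2 by -0.23 (range -0.43 to -0.033). Among LIF and STAT3 target genes 15 of 19 were lower (camera adjusted p = 0.127, but 0.0391 with the stricter filter and 0.0233 without untreated replicate 2, and 0.0233 to 0.966 over all alternatives). The mean of the list was -0.02 log2 and turned to 0.03 with the mean of a gene's probe sets. Socs3 differed by -0.25, -0.27 and -0.37 log2 on 3 probe sets, the one followed with a range of -0.39 to -0.16. Socs1 was 1.57-fold higher with dim signals raised to the lower signal limit. Its measured difference had an interval of -0.03 to 1.60 log2, so no minimum rise is shown.

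No marker of another lineage passed over all probe sets. Of 14 primitive streak and mesoderm markers 11 were higher, with Lmo2 at 1.65 log2 (SE 0.58), Mesp1 at 0.55 and Eomes at 0.25 (camera adjusted p = 0.0904, 0.861 with an estimated correlation). Lmo2 ran from 0.56 log2 without untreated replicate 2 to 2.74 without untreated replicate 1, with untreated signals of 109 and 23.9, and passed in 2 of 11 alternatives (adjusted p 0.0116 to 1.00). The list passed after centring each array on its median (camera adjusted p = 0.0236) and without treated replicate 1 (0.0039), and its adjusted p ran from 0.0039 to 0.962 over all alternatives. Of 18 endoderm markers 13 were higher, with Sox7 at 1.11 log2 and Gata4 at 0.45 (range 0.11 to 0.78, camera adjusted p = 0.151). Foxa1 was 1.51-fold higher with dim signals raised to the lower signal limit. Its measured difference had an interval of -0.11 to 1.52 log2, so no minimum rise is shown. Of 12 epiblast and neuroectoderm markers 8 were lower, with Neurod1 at -0.29, Fgf5 at -0.67 and, the other way, Zic2 at 0.38 (range -0.024 to 0.79, camera adjusted p = 0.0585, 0.750 with an estimated correlation). That list passed in 4 of 14 alternatives, with the stricter filter (0.0480), with the mean of a gene's probe sets (0.0065), without treated replicate 1 (0.0223) and without untreated replicate 2 (0.0233, and 0.0065 to 0.750 over all alternatives). Fgf5 ran from -0.14 log2 without untreated replicate 1 to -1.20 without untreated replicate 2. Trophectoderm and surface ectoderm markers were higher for 9 of 13 genes (camera adjusted p = 0.607). Grhl2 lay at 0.22 (range 0.12 to 0.32) and Ascl2 at -0.30 (range -0.43 to -0.016). Krt19 was 1.25-fold higher with dim signals raised to the lower signal limit. Its groups overlapped, and its measured log2 difference had an interval of -0.34 to 1.65 (range 0.11 to 1.20), so no minimum rise is shown. Germ cell and early embryo markers were higher for 5 of 12 genes (Tex19.1 at -0.08, range -0.12 to -0.033, Kit at 0.23, range -0.0081 to 0.46, camera adjusted p = 0.636). Fibroblast markers, which feeder cells would bring, were higher for 4 of 11 (Cd44 at -0.32, range -0.60 to -0.039, Thy1 at -0.16, Col6a2 at 0.18, range -0.056 to 0.41, camera adjusted p = 0.709).

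Mitochondrial respiration genes were lower as a list by a small amount. Of 25 genes 22 were lower, with Cox4i1 at -0.10 log2, Atp5a1 at -0.11 (range -0.16 to -0.06) and Cycs at -0.09 (range -0.13 to -0.06), and the mean was -0.05 (camera adjusted p = 0.0049). The adjusted p was 0.861 with an estimated correlation and 0.928 by fry, and 0 of the 25 genes passed by limma, with 0 at an unadjusted p under 0.05. The list no longer passed after centring each array on its median (camera adjusted p = 0.0634), without the intensity trend, without untreated replicate 1 (mean -0.02) or without treated replicate 2 (mean -0.01), and its mean was -0.09 without treated replicate 1 and -0.08 without untreated replicate 2 (adjusted p 5.1e-05 to 0.953 over all alternatives). Between arrays numbered 2 and arrays numbered 1 it differed by -0.07 log2 (adjusted p = 1.2e-04), more than between treated and untreated cells.

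In the remaining lists no gene passed, and none had an unadjusted p under 0.05 by limma. Camera gave adjusted p-values of 0.858 for p53 target genes, 0.795 for heat shock and unfolded protein response genes, 0.58 for hypoxia and glycolysis genes, 0.663 for cholesterol synthesis genes, 0.58 for cell cycle genes, 0.420 for ribosomal protein genes and 0.762 for reference genes. Among p53 targets Gtse1 lay at 0.14 log2 (range 0.063 to 0.22) and Sesn2 at -0.15 (range -0.26 to -0.016). Ddit4 lay at 0.21 (range 0.0049 to 0.42) and Atf5 at -0.20 (range -0.33 to -0.072) among heat shock and unfolded protein response genes. Egln1 lay at -0.37 (range -0.61 to -0.082) and Hk2 at 0.12 among hypoxia genes. Of the cholesterol genes Insig1 lay at 0.13 (range 0.0055 to 0.25) and Fdft1 at -0.09 (range -0.39 to -0.067). Of the cell cycle genes Ccne1 lay at 0.15 (range 0.012 to 0.18) and E2f1 at -0.19 (range -0.34 to -0.027). Rpsa differed by -0.06 (range -0.09 to -0.031), Tfrc by -0.09 (range -0.17 to -0.011) and Gusb by 0.14 (range -8.2e-04 to 0.28). Hprt, at -0.40 log2 (range -0.65 to -0.14), read 59.7 ± 8.15 with BMP-2 and 79.5 ± 19.6 without, near the lower signal limit of the tested probe sets. The parent line is Hprt-deficient, so Hprt does not serve as a reference gene in these cells. The mean, the median and the camera direction did not share a sign for the pluripotency, Notch, Wnt, heat shock, hypoxia and reference lists. The mean of 15 lists changed sign in at least 1 alternative, and 0 of these changed means passed. After median centring the means of the BMP pathway, cholesterol and heat shock lists lay below 0, and after quantile normalization that of the ribosomal list lay above 0.

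**Figure D3:**
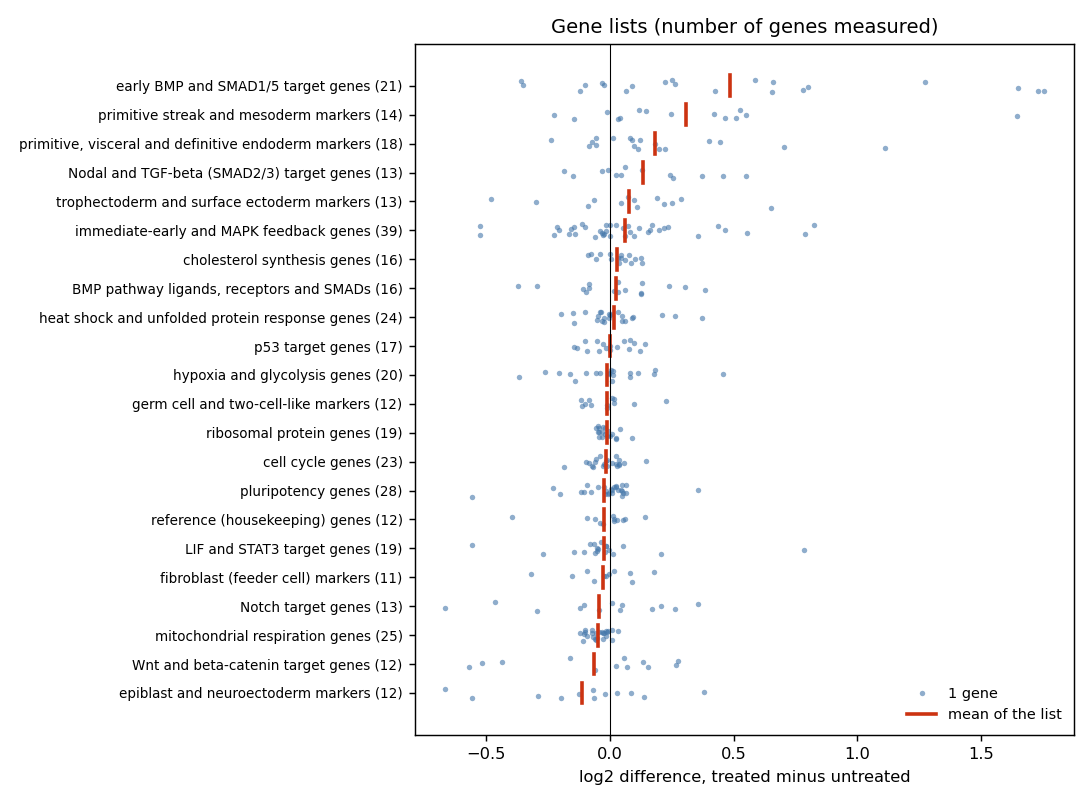
Log2 difference between treated and untreated cells (horizontal axis) of each measured gene (point) in 22 gene lists fixed before the data were examined, with the number of genes in parentheses and a bar at each list's mean. The means run from -0.11 for epiblast and neuroectoderm markers to 0.49 for early BMP target genes, whose 3 points beyond 1.5 log2 are Id1, Id2 and Id3.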

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

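The early BMP list without Id1, Id2 and Id3 was chosen after seeing the data. Id1, Id2 and Id3 stayed higher in 12 alternatives and past the threshold in 11, and Pom121 in 9, with adjusted p-values for Pom121 of 3.3e-06 to 1.00. Without the intensity trend 0 probe sets passed (1023 at an unadjusted p under 0.05), while the prior degrees of freedom went from 7.98 to 2.30. Median centring gave 17 probe sets, the stricter filter 8 and an adjusted p under 0.1 gave 11, each with the same 5 among them. The prior degrees of freedom were 14.2 after median centring and 7.68 with the stricter filter, and the cause was not tested further. Without the filter 4 of the 5 stayed, and Pom121 (adjusted p = 0.104) did not. Leaving out 1 array gave 16 to 141 probe sets, with 1 array then assumed to vary like the others, and the cause was not tested. The number of lists called moved from 2 to 4 with the stricter filter, 3 without the filter, 3 with the mean of a gene's probe sets, 1 without the intensity trend, 0 with an estimated correlation and 1 with fry, and was 4 without treated replicate 1, 1 without treated replicate 2, 1 without untreated replicate 1 and 5 without untreated replicate 2. Median centring kept 2, with the primitive streak list in place of the mitochondrial one. The shift of the early BMP list was 0.49 log2 with an estimated correlation too, where its adjusted p was 0.235, and it passed in every other setting run, at 0.28 to 0.71.

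With the replicate number as a block, 11 probe sets passed (10 higher, 1 lower), with the same 5 among them. The deviations of same-numbered arrays correlated at 0.15 across probe sets. The SD of the log2 difference was 0.345 and 0.353 for the 2 same-numbered pairs and 0.370 to 0.385 for the other pairs. By r these pairs stood less apart (0.987 and 0.985 against 0.984 to 0.985). Some signal thus went with the replicate number, which the main fit leaves out, but 2 pairs do not establish a shared origin. The block's own term called 9 probe sets, among them Smad7 (1.33 log2 higher in replicate 2, on the probe set that gave 0.16 for BMP-2). Split by replicate number, 0 probe sets passed but 2905 had an unadjusted p under 0.05, against 829 by treatment and 1452 by treatment with the block. The other split gave 0 and 633, and 3 splits are too few for a share under 0.05.

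Of 114 genes followed, 19 changed sign in some setting. None of these passed in any setting, and the cause was not tested. Leaving out 1 array also leaves the replicate numbers unequal between the groups. Median centring turned Sox2 (-0.016). The mean of a gene's probe sets turned Trib3 (0.059), Srebf2 (-0.026), Mcm2 (0.018) and Rps24 (0.057). When arrays were left out, the log2 difference ran from -0.17 to 0.35 for Smurf2, -0.23 to 0.0076 for Eif1a, -0.23 to 0.060 for Sycp3, -9.3e-05 to 0.12 for Actb, -0.21 to 0.36 for Egr1, -0.019 to 0.049 for Sox2, -0.20 to 0.15 for Tob1, -0.056 to 0.41 for Col6a2, -0.13 to 0.0016 for Vim, -0.21 to 0.0078 for Smurf1, -0.024 to 0.79 for Zic2, -0.095 to 0.0019 for Rps24, -8.2e-04 to 0.28 for Gusb, -0.029 to 0.50 for Fos, -0.0081 to 0.46 for Kit and -0.10 to 0.0049 for Rpl27. Signal over background limits the dim probe sets, whose log2 values spread most.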

Other observations

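The tests on the lineage markers were chosen only after the result was seen, and the others were set down before, apart from the weighted mean and the split of the proneural targets by brightness. The 18S ribosomal RNA readings of untreated replicate 2 and its Actb and Gapdh ratios were also examined, after they had been noticed, and are given as values without an explanation.

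Probe sets outside the comparison, too dim or controls, numbered 18079. By limma over all deposited probe sets 0 of these passed (smallest adjusted p = 0.788). At an unadjusted p under 0.05 there were 919, near the share of 0.05 that chance alone gives. Several probe sets followed the replicate number instead of the treatment. Cotl1 averaged 509 on the arrays numbered 1 and 160 on those numbered 2, Srsf6 2661 and 4851, and Sptlc1 211 and 575. Pluripotency genes as a list differed by -0.06 log2 between arrays numbered 2 and 1 (camera adjusted p = 7.3e-04).

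Gadd45g (-0.95 log2) and Dll1 (-0.67 log2), both known targets of proneural basic helix-loop-helix factors, which Id proteins oppose, were among the lower signals, without passing the test, and the hypothesis was that other targets were lower as well. The mean difference of 19 other targets was 0.011 log2 (95% interval across genes -0.08 to 0.10, camera p = 0.235, 0.326 with an estimated correlation). Weighted by precision it was -0.05 (-0.12 to 0.01), so no joint fall was seen on these arrays. All targets were read on the same arrays. The intervals across genes thus leave out error shared by the genes and set no limit on a fall. The 9 brighter targets averaged -0.08, with Neurod1 at -0.29, Btg2 at -0.21 and Tubb3 at -0.20. The 10 dimmer ones averaged 0.09, Mfng at -0.30 being one of these. A fall of bright targets thus stays open. Noise of single probe sets may account for both values, since the number of other kept probe sets of these genes was 0, and an effect on these 2 genes alone also stays open.

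The call on Pom121 rests on 1 probe set. Scaling between arrays is argued against by the difference after quantile normalization, 0.78 log2. Another transcript read by this probe set may account for the rise, since the other Pom121 probe set differed by -0.048 log2 where the called one differed by 0.78. A change in 1 form of the Pom121 transcript would give the same values and stays open. The probe sequences that would tell these apart were not used here.

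Markers of primitive streak, mesoderm and endoderm were higher together, 24 of 32 genes, with a mean of 0.24 log2 (95% interval across genes 0.10 to 0.38) and a median of 0.12, but the mean was 0.11 without treated replicate 2, 0.37 without treated replicate 1 and 0.01 for the 11 genes left by the stricter filter, and the 2 lists differed by 0.17 and 0.15 log2 between arrays numbered 2 and 1. For the hypothesis of a rise of lineage markers within 1 h of BMP-2, fry gave a p of 0.237 for both lists together and camera 0.0040, or a p of 0.208 with an estimated correlation, which leaves it open. Drift of dim probe sets may also account for it, with the median at percentile 98.5 of 10000 random lists matched on signal, above the bar of 0.11 log2 first set against drift. After that value was known the bar was raised to percentile 99.9, to allow for the 22 lists searched, a fry p under 0.05 was required as well, and by the first bar drift would have been excluded. Since the lists were picked for their high values, that exclusion was not kept, and these explanations cannot be told apart with 2 arrays per group.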
